A study of Homo sapiens with 16 samples.

How the data were processed

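Bulk RNA-seq was available for 16 libraries of HEK293 cells, an established human line of embryonic kidney origin. They fell into 8 groups of 2: parental cells, cells carrying the empty expression plasmid, and cells carrying 1 of 6 cloned transcripts of LINC01016, named T1, T2, CU1, CU2, CU1ENC and CU1ENU in the labels. Per the labels' protocols, 5 micrograms of a pcDNA3.0 plasmid were delivered with a lipid reagent to cells in 60 mm plates and RNA was taken 48 hours later. RNA integrity numbers were above 9, and paired-end libraries kept strand information through dUTP marking. Groups and replicate numbers were taken from the sample titles.

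The authors deposited whole-number read counts per gene, with no normalization. Per the file headers, the counts were made with featureCounts 2.0.1 in paired mode with strand option 2, over exons grouped by gene in the Ensembl release 101 annotation, and coordinates below are from those headers. Per the submitters' processing notes, the tools also included HISAT2 and DESeq2 and the genome build was GRCh38.p13. Their versions and the alignment settings are not given in the sources used here. How reads that fit several places were treated is likewise not stated, so counts of pseudogenes and near-identical copies are uncertain. Strand-aware counting keeps a gene and its antisense partner apart only as far as the strand marking held. Of 60671 genes in the table, 60401 were given a symbol by identifier from the supplied gene names, and no column was left without a sample.

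Library totals ran from 15040770 to 17255935 counts. Libraries of a group were compared first for being deposited more than once: chi-square per degree of freedom between replicates ran from 6.76 in T2 to 19.0 in T1, far above sampling noise, so each was kept as its own replicate. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals cover counting error only, and a fold against a count floor leaves out the counting error of the other group. A fold against a group at 0 was computed against a floor of 3 counts over the group, with 95% exact intervals elsewhere.

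Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 19316, and scaled by TMM factors between 0.974 and 1.03. Quasi-likelihood F-tests with robust shrinkage used a model of 8 group means over all 16 libraries, which left 8 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are given on the log2 scale with standard errors (SE). The SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. Intervals of fold changes from the fit rest on it and are approximate. CPM of LINC01016 and its antisense gene are scaled by the deposited total, and CPM of other genes are TMM-scaled. With groups of 2 against 2, an exact permutation of 1 gene cannot give a p below 0.33, so calls rest on the model shared over genes. The comparisons were empty vector against parental cells, each isoform and the mean of the 6 isoforms against empty vector, each isoform against the mean of the other 5, and an F-test over the 6 isoforms.

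The labels number replicates 1 and 2 in every group. After subtraction of group means, same-numbered libraries deviated together in all 28 pairs of groups (r from 0.162 to 0.442, median 0.248), so the numbers pair the libraries. This comes from the data, as no label says what a number marks. A fit with the replicate number as a block left 7 residual degrees of freedom, and its common dispersion was 0.00436 against 0.0184 without it. Blocked values are given beside the main calls and counts that they change, but not for the member counts of every list.

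Gene lists from general knowledge, 27 in all, were tested against all other genes with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. Lists needed at least 5 tested members, which 25 had, and p-values were adjusted over those 25. Rules, lists, comparisons and most alternatives were fixed before the data were examined. The rule for named genes took LINC01016, then for each comparison with a control the 8 largest rises, 8 largest falls and 4 lowest p in each direction among passing genes. These needed a mean log2 CPM of at least 1, a symbol that is not a clone name, and both libraries of a group beyond both of the other. Against other isoforms it took the 5 largest changes each way, for the F-test 12 genes of lowest p, for a called list up to 4 members of lowest p in its direction, and 5 genes of lowest p where none passed. The F-test genes and those 5 had to meet the same expression and symbol limits. For the isoform comparisons the text names only the leading gene of each part of that rule, and for the F-test the leading 3. This narrowing was made after values had been seen. Genes within 500 kb of LINC01016 were also examined.

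The code was tested on counts simulated from the empty vector means, with the spreads and the replicate term of the blocked fit. That replicate term was the same in every group, and genes of very low count were not among those changed. In a simulated T1 against empty vector comparison over 18850 genes, changes of 1.5, 2 and 4-fold were called in 20.9%, 50.8% and 78.8% of changed genes, with 0 false calls. For empty vector against parental over 18822 genes the shares were 22.7%, 58.5% and 77.3%, again with 0 false calls. With the block those shares rose to 46.3%, 68.7% and 86.4% with 13 false calls in the T1 simulation, and to 40.9%, 69.2% and 90.9% with 8 in the other.

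Alternatives covered RLE normalization, DESeq2 1.42.0 with and without the block, no low-count filter, the block, a 2-fold minimum, LINC01016 left out, each library left out, only the compared groups in the fit, and parental cells as the control. GC content came from the supplied reference annotation.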

Results

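LINC01016 is a long non-coding RNA gene of human testis, and each of 6 cloned transcripts was expressed in HEK293 cells, in which the submitters state that the gene is silent. The question was which genes respond to each transcript and whether transcripts differ. Messenger and other RNA was counted by gene in 16 libraries, 2 for each of 8 groups, with totals from 15040770 to 17255935 counts and between 25529 and 27461 genes with a count. On a principal component analysis of the libraries, the leading axis (28.6% of variance) set the 2 parental libraries, at -70.8 and -57.8, apart from the 14 transfected ones, which lay between -2.41 and 29.8. It also split the transfected ones by replicate number, replicate 1 from -2.41 to 1.96 and replicate 2 from 11.1 to 29.8. So did the second axis (18.5%), with replicate 1 from -28.1 to -14.5 and replicate 2 from 4.69 to 25.9.

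LINC01016 (ENSG00000249346, GRCh38.p13 chromosome 6, 33867506 to 33896914, minus strand, 5055 exonic bases) was high in every library given a transcript and near 0 elsewhere. It had 0 counts in both parental libraries and 1 and 0 counts in the empty vector libraries. Mean CPM was 6425 ± 269 in T1, 4969 ± 305 in T2, 8488 ± 3323 in CU1, 2839 ± 338 in CU2, 6903 ± 560 in CU1ENC and 10372 ± 2764 in CU1ENU (SD, n = 2 each). It thus took from 0.260% to 1.23% of all counts in single libraries with a transcript. Relative to empty vector, CU2 stood 89804-fold higher (95% counting interval 16118 to 3547100) and CU1ENU 327183-fold (58722 to 12923100), with the other isoforms between them. Relative to a floor of 3 counts in parental cells, CU2 was 31298-fold and CU1ENU 114026-fold higher, with exact lower limits of 25452 and 92732. In edgeR, LINC01016 rose in all 6 isoforms against empty vector, with adjusted p from 1.53e-08 in CU1ENU to 4.52e-08 in CU2. Gene counts do not separate the 6 transcripts, since each library adds up reads over all annotated exons.

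**Figure D1:**
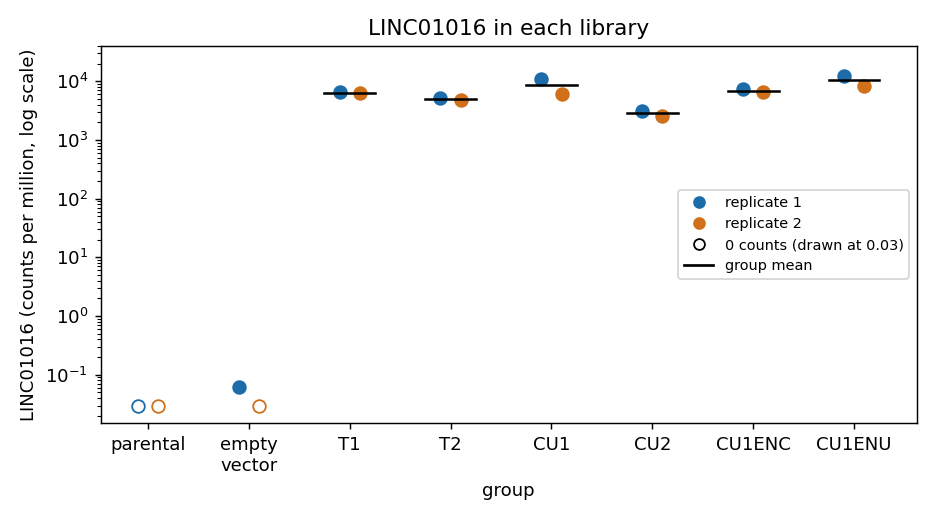
LINC01016 in CPM (log scale) in each of the 16 libraries, by group, with replicate 1 and replicate 2 in different colours, bars at group means, and open circles for libraries with 0 counts drawn at 0.03. The 12 libraries with a transcript lie between 2600 and 12326 CPM, and the 4 control libraries have 0 or 1 count.

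The gene on the opposite strand, ENSG00000233183 (chromosome 6, 33891327 to 33927631, plus strand), shares 862 exonic bases with LINC01016, 17.1% of the LINC01016 exons. It had 0 counts in parental cells and 2 in empty vector, and in isoform libraries its counts were 2.92% to 8.08% of those of LINC01016. Mean CPM ran from 92.1 ± 3.31 in CU2 to 562 ± 317 in CU1ENU (SD, n = 2). Against empty vector this was 1453-fold in CU2 (95% counting interval 402 to 12007) and 8861-fold in CU1ENU (2453 to 73174). It rose by edgeR in T1 (adjusted p = 0.0157), T2 (0.0214), CU1 (0.0260), CU1ENC (0.0167) and CU1ENU (0.0133), and did not pass in CU2. With the replicate block the calls in T2 (adjusted p = 0.0552) and CU1 (0.0723) were lost, and leaving out any library of empty vector, T1, T2 or CU2 ended the call in every isoform. The 2 genes overlap, so this value is uncertain as a measure of antisense transcription.

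Empty vector cells differed widely from parental cells. MAFF, a small Maf factor and immediate-early gene, was 10.2-fold higher (28.2 ± 2.06 against 2.76 ± 0.113 CPM, SD, n = 2; log2 fold change 3.35 ± 0.28 SE, adjusted p = 2.72e-05). ATF3 (ENSG00000162772), a stress-induced factor, was 5.15-fold higher (459 ± 6.55 against 89.2 ± 15.5 CPM) with an adjusted p of 1.71e-06. ANKRD1, a cardiac ankyrin repeat protein also induced by stress, rose by 3.68 ± 0.54 on the log2 scale from 38.4 ± 17.3 CPM. Leading the falls under the naming rule was ITGA8, an integrin subunit, at a log2 fold change of -2.87 ± 0.56. IGFBP5, which binds insulin-like growth factors, followed at -2.28 ± 0.61. In all, 1818 genes rose and 1274 fell of 19316 tested, and 557 and 136 of these changed at least 2-fold.

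With the replicate block 6626 genes passed (3551 up and 3075 down), among them 3089 of the 3092. Of the 6626, 1094 changed at least 2-fold. Leaving out a single library of either group lowered the count to 1551 and 1365 (without empty vector replicate 1 and replicate 2) and to 1436 and 1535 (without parental replicate 1 and replicate 2). Without at least 1 of these 4 libraries, ITGA8, IGFBP5, TMEM37, DGKK, QPRT, COL21A1, SEMA5A, C9orf152, BAG3, CENPF, FDPS, RPL13A, ATP5PD and SDHC no longer passed, while every other gene named as changed kept its call. The highest adjusted p was 0.237, for QPRT without parental replicate 1, and IGFBP5 and QPRT also lost the call without some isoform libraries.

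Among genes that met the naming rule, the largest rises belonged to 3 annotated pseudogenes. These were KLKP1 (6.13 ± 0.56), IRS3P (6.02 ± 0.83) and ASNSP1 (4.36 ± 0.59), whose counts are uncertain because copies of a gene can share reads. Besides ANKRD1 and MAFF, other large rises were C9orf152 (3.36 ± 0.69), SCG2, a granin of secretory vesicles (3.16 ± 0.43), and XKR7 (3.08 ± 0.49). The snoRNA host genes SNHG15 (1.63 ± 0.10) and SNHG17 (1.67 ± 0.11) and the small heat shock protein gene HSPB8 (1.51 ± 0.10) rose with an adjusted p of 1.80e-06 or below. Further large falls were TMEM37 (-2.14 ± 0.50), DGKK, a diacylglycerol kinase (-2.05 ± 0.48), QPRT, an enzyme of NAD synthesis (-2.04 ± 0.61), COL21A1, a collagen (-1.95 ± 0.51), B3GALT4 (-1.77 ± 0.34) and SEMA5A, a semaphorin (-1.73 ± 0.38). Falls with a low p included CPE, a prohormone-processing enzyme (-0.85 ± 0.09), ARL6IP1 (-0.72 ± 0.08) and NRCAM, a cell adhesion gene (-1.05 ± 0.12).

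**Figure D2:**
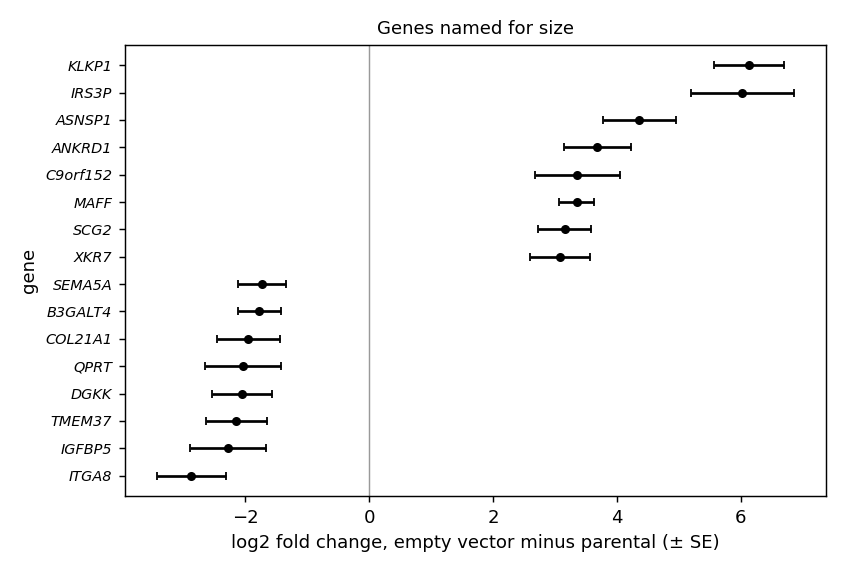
Log2 fold change of empty vector over parental cells (horizontal axis) with SE bars for the genes named by size, 1 gene per line. KLKP1, at 6.13, lies farthest to the right and ITGA8, at -2.87, farthest to the left.

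Immediate-early and stress response lists rose. Of 31 immediate-early genes 23 rose and 1 fell (adjusted over the list alone, 24 and 1; camera adjusted p = 1.34e-26), with JUN at 1.20 ± 0.13, FOSB at 1.93 ± 0.24 and KLF10 at 1.17 ± 0.11. Of 35 genes of the integrated stress response, the ATF4 program that adjusts amino acid supply and translation, 21 rose and 1 fell (24 and 1 adjusted over the list alone; 2.55e-19). Examples were DDIT3 (1.30 ± 0.10), PPP1R15A (2.09 ± 0.18) and the amino acid transporter subunit SLC3A2 (1.92 ± 0.19). These 2 lists also passed with an estimated correlation, with adjusted p = 0.00251 and 0.00168.

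Ribosome biogenesis genes rose in 17 of 30 cases and fell in 0 (20 and 0 adjusted over the list alone; camera adjusted p = 4.25e-11), including RRP12 (1.39 ± 0.16) and NOP14 (0.63 ± 0.09). NF-kB and inflammatory genes rose in 7 of 19 (7 adjusted over the list alone; 9.37e-06), among them RELB (2.09 ± 0.18) and TNFAIP3, a feedback inhibitor of the pathway (1.55 ± 0.15). Both calls were lost with an estimated correlation (adjusted p = 0.349 and 0.286) and held there once the replicate block was added (adjusted p = 0.0235 and 0.0424). For the endoplasmic reticulum unfolded protein response 8 of 25 rose (10 adjusted over the list alone; 8.75e-05), such as XBP1 (0.83 ± 0.10), HERPUD1 (1.30 ± 0.25) and MANF (0.63 ± 0.11). Heat shock and chaperone genes rose in 6 of 22 (7 adjusted over the list alone; 0.0136), with BAG3 at 0.99 ± 0.23 and CHORDC1 at 0.70 ± 0.12. With an estimated correlation the adjusted p was 0.507 for the unfolded protein response and 0.652 for heat shock.

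Replication-dependent histone genes rose in 9 of 27 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00477, and adjusted p = 0.286 with an estimated correlation), for instance H4C8 (1.12 ± 0.17) and H2BC5 (1.14 ± 0.22). Histone genes have near-identical copies, so their counts are uncertain. In the estrogen response list 6 of 17 rose and 2 fell (8 and 4 adjusted over the list alone; camera up, adjusted p = 0.00805, and adjusted p = 0.115 with an estimated correlation), though its median was -0.03 and its mean 0.27. Its members that rose were led by RARA, a retinoic acid receptor (1.38 ± 0.12), STC2, a secreted glycoprotein (1.28 ± 0.14), EGR3, an immediate-early factor (1.73 ± 0.22), and XBP1, which also stands in the unfolded protein response list.

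Lists of cell division, cholesterol, ribosomal protein and respiratory genes fell. Of 30 G2/M genes 0 rose and 7 fell (10 adjusted over the list alone; camera adjusted p = 0.000513), such as TOP2A (-0.58 ± 0.08), CDK1 (-0.59 ± 0.09), ASPM (-0.49 ± 0.07) and CENPF (-0.38 ± 0.08). Cholesterol synthesis genes fell in 5 of 25 (5 adjusted over the list alone; 0.000786), among them FDPS (-0.45 ± 0.10). Of 78 cytosolic ribosomal protein genes 12 fell and 1 rose (15 and 1 adjusted over the list alone; 8.75e-05), with RPL13A at -0.52 ± 0.10 and RPL3 at -0.40 ± 0.08. Nuclear-encoded respiratory chain subunits fell in 6 of 60 and rose in 1 (3 and 1 adjusted over the list alone; 0.0134), including ATP5PD (-0.45 ± 0.11) and SDHC (-0.38 ± 0.09). All 4 calls were lost with an estimated correlation, with adjusted p = 0.652 for G2/M, 0.507 for cholesterol, 0.699 for ribosomal proteins and 0.722 for respiratory subunits.

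Interferon-stimulated genes, which carry out antiviral defence, stood apart. All 43 had a positive fold change and the list was called up by camera (adjusted p = 5.18e-05), yet 0 of 43 passed singly, over all genes or adjusted over the list alone. Without the low-count filter edgeR called 42 of them among 3381 genes, in a fit that ignored the spread of single genes. The fitted median was 2.72, or 2.48 with IFNB1 and IFNL1 set to their folds against a floor of 3 counts. These 2 interferon genes had 0 counts in parental cells. Against that floor they were 3.49-fold and 5.58-fold higher in empty vector, without passing (adjusted p = 0.164 and 0.119). ISG15 measured 129 ± 72.1 CPM against 9.97 ± 0.458 (log2 fold change 3.70 ± 1.60, adjusted p = 0.161). With an estimated correlation the list had an adjusted p of 0.719, and with the replicate block 8 members rose, among them ISG15 (adjusted p = 0.0210), IFNB1 (0.0247) and IFNL1 (0.00426). DESeq2 also called ISG15 (adjusted p = 0.0236) and IFNB1 (0.0484).

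**Figure D3:**
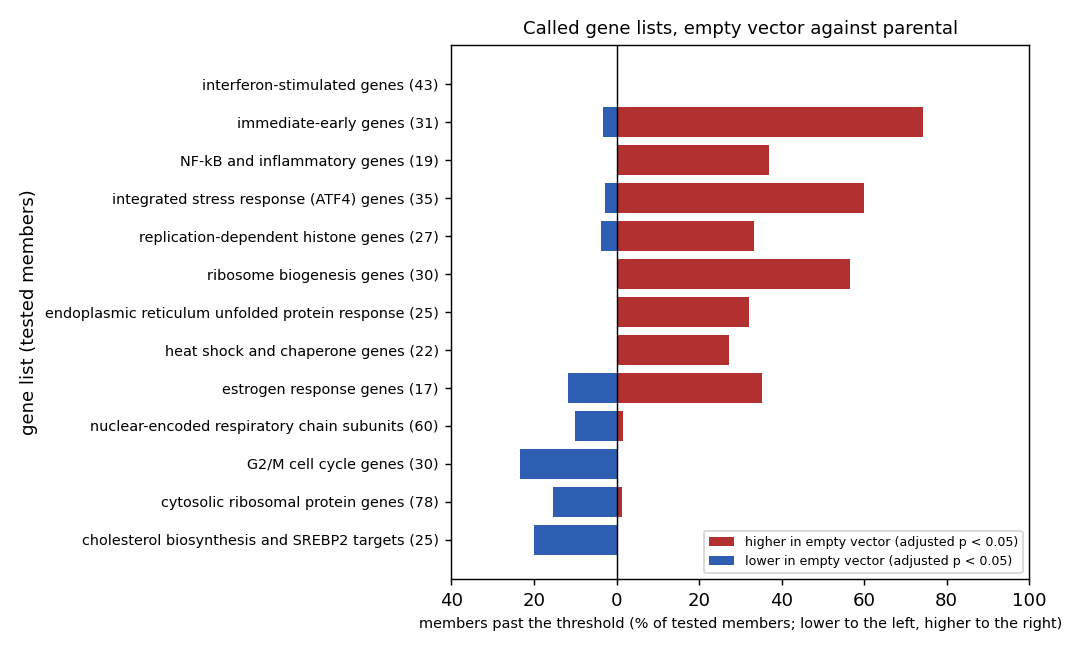
Share of tested members (percent, with the number tested in brackets) that were higher (red, to the right) or lower (blue, to the left) in empty vector than in parental cells at an adjusted p under 0.05, for the 13 called lists. Immediate-early genes show the longest bar, 23 of 31, and interferon-stimulated genes show none.

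Of the remaining lists, 12 were not called by camera. Members up and down were 5 and 5 of 25 for p53 targets, 2 and 3 of 30 for G1/S and DNA replication, 4 and 3 of 27 for hypoxia and glycolysis, 6 and 0 of 31 for SR proteins and hnRNPs, and 0 and 0 of 13 for mitochondrially encoded genes. They were 0 and 1 of 5 for metallothioneins, 2 and 1 of 14 for Wnt targets, 1 and 1 of 12 for germ cell genes and 1 and 2 of 18 for neuronal genes. Markers of other cell types gave 0 and 3 of 13 for fibroblasts, 1 and 0 of 8 for keratinocytes and cervical or endometrial epithelium, and 2 and 0 of 6 for kidney tubule. Too few members were measured to test the polymerase III and small nuclear RNA list (3 of 20) or the leukocyte and erythroid markers (2 of 18). With the replicate block 16 lists were called, the additions being p53 targets (down, adjusted p = 0.000105), SR proteins and hnRNPs (up, 0.0231) and the keratinocyte and epithelial markers (up, 0.0128). These 3 were lost with an estimated correlation in the blocked fit (adjusted p = 0.227, 0.639 and 0.109). Whether these changes came from plasmid, lipid reagent or handling cannot be separated, since parental cells were the only untransfected group.

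Against empty vector, no gene outside the LINC01016 locus passed in any of the 6 isoforms by edgeR with its low-count filter. Without the filter, in a fit that ignored the spread of single genes, 30 passed in T1, 33 in T2, 15 in CU1, 71 in CU2, 5 in CU1ENC and 0 in CU1ENU. With the filter, LINC01016 and ENSG00000233183 were the 2 genes called in T1, T2, CU1, CU1ENC and CU1ENU, and LINC01016 was the 1 gene called in CU2. Unadjusted p under 0.05 was reached by 210 genes in T1, 449 in T2, 314 in CU1, 237 in CU2, 177 in CU1ENC and 247 in CU1ENU, where 966 of 19316 would be reached by chance alone. These counts lie below chance, so p-values of this fit ran too high, and the shortage is no sign that effects are absent. DESeq2 also called 0 genes outside the locus in T1, T2, CU1, CU2 and CU1ENU and called BCYRN1 in CU1ENC, a call lost in DESeq2 with the replicate block (0 genes outside the locus). In edgeR with the block the unadjusted counts were 567, 1464, 932, 585, 422 and 687, still with 0 adjusted calls outside the locus. The 1464 genes of T2 exceeded the 966 of chance. In the T1 comparison without the block, 71.1% of genes had a 95% interval inside a 2-fold change either way. For the others a 2-fold change was not excluded. With the block the share was 75.6%, and it was 99.4% among the 10846 genes above a mean of 10 CPM.

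BCYRN1, a polymerase III transcript related to Alu repeats, had 1264 and 2426 counts in the CU1ENC libraries against 75 and 113 in empty vector (117 ± 49.8 against 5.92 ± 1.87 CPM, log2 fold change 4.31 ± 1.02). Its adjusted p was 1.00 in edgeR and 0.0193 in DESeq2, and it was no longer called in DESeq2 with the replicate block. Parental replicate 1 also had 1026 counts and parental replicate 2 had 85. This difference enters the spread of the edgeR fit, which covers all libraries, so the edgeR result does not speak against a change in CU1ENC. Its repeat-derived sequence makes the count uncertain.

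T1 carried small upward shifts of stress lists against empty vector, with 0 members passing singly in any list, adjusted over the list alone as well. Called up were the integrated stress response (27 of 35 positive, median 0.12, camera adjusted p = 0.000276), immediate-early genes (26 of 31, 0.13, 0.000587), the unfolded protein response (21 of 25, 0.07, 0.00234), NF-kB genes (16 of 19, 0.14, 0.00302) and hypoxia and glycolysis genes (22 of 27, 0.07, 0.0226). Leading members, none past the threshold, were TRIB3, a kinase-like inhibitor (0.30 ± 0.12), MAFF (0.43 ± 0.23), the chaperone gene DNAJB9 (0.33 ± 0.14), PTGS2, an inducible cyclooxygenase (0.60 ± 0.25), and PFKFB3, a regulator of glycolysis (0.16 ± 0.13). With an estimated correlation every call ended, with adjusted p between 0.161 and 0.854, and the replicate block added ribosome biogenesis genes (up, adjusted p = 0.00163, and adjusted p = 0.358 there with an estimated correlation). Outside the locus, DLL1, a Notch ligand, led in p (log2 fold change 0.48 ± 0.13, adjusted p = 1.00). That ranking covers only genes within the expression and symbol limits for naming.

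T2 showed the most called lists, 8, again with 0 members passing singly or adjusted over the list alone. Cytosolic ribosomal proteins (75 of 78 positive, median 0.12, camera adjusted p = 1.17e-10), respiratory chain subunits (54 of 60, 0.11, 2.30e-08), interferon-stimulated genes (42 of 43, 0.64, 0.000571), heat shock genes (21 of 22, 0.09, 0.000814), G1/S genes (25 of 30, 0.07, 0.00368) and cholesterol genes (19 of 25, 0.08, 0.0195) were called up. Called down were immediate-early genes (7 of 31 positive, median -0.11, 0.0195) and mitochondrially encoded genes (0 of 13 positive, -0.28, 0.0236). The examples were RPL17 (0.33 ± 0.15), ATP5PD (0.28 ± 0.11), IFNB1 (1.54 ± 1.06), DNAJA1, a co-chaperone (0.22 ± 0.08), GINS2 of the replication complex (0.24 ± 0.10), FDPS (0.20 ± 0.10), FOSB (-0.72 ± 0.22) and MT-ND2 (-0.31 ± 0.30). Without empty vector replicate 1, MT-ND2 turned to 0.09. The mean of the mitochondrial list differed from empty vector by -0.48 in replicate 1 and 0.03 in replicate 2. Estimated correlation ended every call, with adjusted p of 0.755 or 0.909, and the block added hypoxia and glycolysis genes (up, adjusted p = 0.0202, and adjusted p = 0.388 there with an estimated correlation). Within the limits for naming, CABIN1, a calcineurin-binding protein gene, had the lowest p outside the locus (-0.29 ± 0.08, adjusted p = 1.00).

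CU2, the isoform with the least LINC01016 RNA, was called up for interferon-stimulated genes (42 of 43 positive, median 1.14, camera adjusted p = 2.80e-10), NF-kB genes (18 of 19, 0.28, 0.000240), the integrated stress response (29 of 35, 0.08, 0.00210), heat shock genes (19 of 22, 0.07, 0.0128) and the unfolded protein response (21 of 25, 0.08, 0.0205). The mean of the interferon list lay above empty vector by 1.14 in replicate 1 and 1.15 in replicate 2 on the log2 scale. For T2 these differences were 0.50 and 0.95. In T1, CU1, CU1ENC and CU1ENU the list lay above empty vector in replicate 1, by 0.34 to 1.08, and below it in replicate 2, at -0.56 to -1.15. Members were led by CCL5, a chemokine (1.47 ± 0.93), NFKB1 (0.25 ± 0.11), WARS1 (0.28 ± 0.13), DNAJA1 (0.21 ± 0.08) and DERL1 (0.17 ± 0.09), none past the threshold over all genes or adjusted over the list alone. All 5 calls ended with an estimated correlation (adjusted p from 0.427 to 0.997), and the block added immediate-early genes (up, adjusted p = 0.0289), G1/S genes (up, 0.0216) and hypoxia and glycolysis genes (up, 0.0476). These 3 were lost too with an estimated correlation in the blocked fit (adjusted p = 0.731, 0.569 and 0.381). RFPL4A had the lowest p outside the locus within the limits for naming (0.55 ± 0.15, adjusted p = 1.00).

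**Figure D4:**
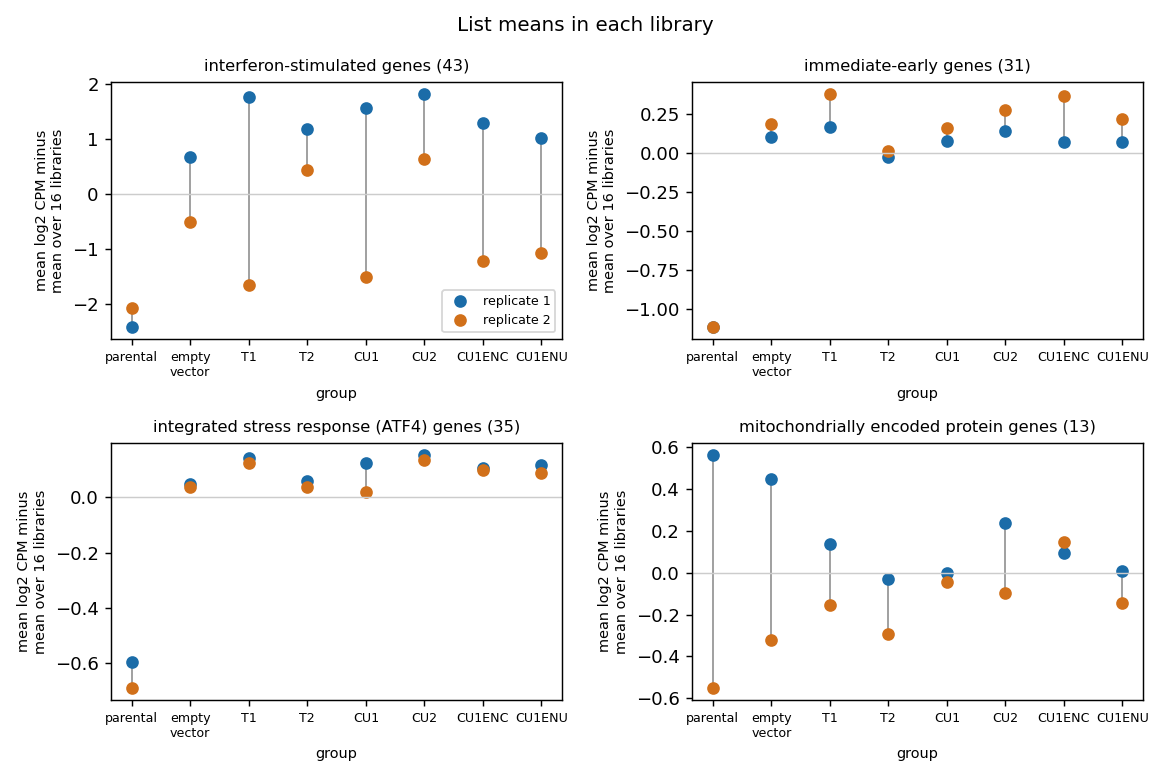
Mean log2 CPM of the members of 4 lists in each library, minus its mean over the 16 libraries, by group, with replicate 1 in blue and replicate 2 in orange joined by a line. Interferon-stimulated genes are higher in replicate 1 of all 7 transfected groups, while in parental cells replicate 1 minus replicate 2 is -0.34.

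CU1 had 2 called lists, the unfolded protein response (19 of 25 positive, median 0.10, camera adjusted p = 0.0187) and heat shock genes (20 of 22, 0.09, 0.0132), with DNAJB9 at 0.27 ± 0.14 and DNAJA1 at 0.16 ± 0.08. CU1ENU had 3, the same pair (22 of 25 and 19 of 22 positive, medians 0.09 each, 0.00591 for both) and the integrated stress response (28 of 35, 0.07, 0.0297), with DDIT3 at 0.28 ± 0.09, DNAJB9 at 0.27 ± 0.14 and HSPA8 at 0.20 ± 0.09. CU1ENC had 0. No member passed singly or adjusted over the list alone, and with an estimated correlation adjusted p was 0.973 for both CU1 lists and between 0.549 and 0.853 for those of CU1ENU. The heat shock mean exceeded empty vector by 0.032 in replicate 1 and 0.199 in replicate 2 for CU1. These differences were 0.012 and 0.184 for CU1ENU, 0.048 and 0.151 for CU2, and 0.12 in both for T2. All isoforms were set against the same empty vector libraries, so a list called in several isoforms is not independent evidence. The replicate block added hypoxia and glycolysis genes in CU1 (adjusted p = 0.0165), CU1ENU (0.00264) and CU1ENC (0.0116), G1/S genes in CU1ENU (0.0285), and in CU1ENC the integrated stress response and immediate-early genes (0.00377 each), NF-kB genes and the unfolded protein response (0.0116 each), all upward. With an estimated correlation in the blocked fit all of these ended, with adjusted p = 0.435 in CU1, 0.219 and 0.442 in CU1ENU, and between 0.318 and 0.846 in CU1ENC. Within the limits for naming, the lowest p outside the locus belonged to TOB1-AS1 in CU1 (-1.17 ± 0.33) and BCYRN1 in CU1ENC. In CU1ENU it belonged to UQCRHL, a respiratory chain paralogue (-1.04 ± 0.30), and each of these genes had an adjusted p of 1.00.

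The mean of the 6 isoforms against empty vector gave the same 2 genes of the locus and 0 others by edgeR and DESeq2 (290 at an unadjusted p under 0.05, and 779 with the block). It gave 7 lists called up: the unfolded protein response (21 of 25 positive, median 0.07, camera adjusted p = 0.00329), heat shock (20 of 22, 0.06, 0.00329), integrated stress response (26 of 35, 0.07, 0.00727), interferon-stimulated genes (42 of 43, 0.56, 0.0107), hypoxia and glycolysis (22 of 27, 0.07, 0.0107), G1/S (27 of 30, 0.03, 0.0125) and NF-kB (14 of 19, 0.13, 0.0226). Members named were DNAJB9 (0.25 ± 0.11), DNAJA1 (0.15 ± 0.06), TRIB3 (0.21 ± 0.09), IFNB1 (1.15 ± 0.89), PDK1 (0.15 ± 0.07), PCNA (0.12 ± 0.06) and PTGS2 (0.34 ± 0.20), none past the threshold. The mean of the interferon list lay above empty vector by 0.757 in replicate 1 and stood at -0.220 in replicate 2. For the heat shock list these differences were 0.024 and 0.147. DPH5, an enzyme of diphthamide synthesis, came lowest in p outside the locus within the limits for naming (0.27 ± 0.08, adjusted p = 1.00). With an estimated correlation every list call ended, with adjusted p between 0.219 and 0.937.

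When parental cells served as the control, 3758 genes passed in T1, 2278 in T2, 2593 in CU1, 3177 in CU2, 3362 in CU1ENC and 2888 in CU1ENU, and 5657 for their mean. Of the 3092 genes of empty vector against parental, these included 2732, 1933, 2170, 2528, 2640, 2351 and 3024 in the same direction and 0 in the opposite one. The libraries of parental cells enter both sides of each overlap.

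Among the 6 isoforms the F-test called 0 genes in edgeR. Its DESeq2 counterpart, a likelihood ratio test, called 2, BCYRN1 (adjusted p = 4.87e-06) and LINC01016 (9.33e-06). In edgeR 98 had an unadjusted p under 0.05 against 966 by chance, so these p-values too ran high. With the block edgeR again called 0, with 617 at an unadjusted p under 0.05 and MAFF lowest. Without it, LINC01016 had the lowest unadjusted p (9.47e-05), ahead of BCYRN1 (0.00187) and CENATAC, a splicing-associated gene (0.00461), each with an adjusted p of 1.00. With LINC01016 itself, CU2 lay lowest against the other 5 isoforms (log2 fold change -1.35 ± 0.19) and CU1ENU highest (0.90 ± 0.16), with adjusted p = 0.362 and 1.00. CU2 passed in DESeq2 (adjusted p = 6.50e-06), and also in edgeR without either CU1 library, and CU1ENU passed without CU1 replicate 1. The values for CU1, CU1ENC, T1 and T2 were 0.56 ± 0.16, 0.19 ± 0.17, 0.07 ± 0.17 and -0.37 ± 0.18.

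Each isoform against the mean of the other 5 gave 0 genes in edgeR, with 207 to 450 at an unadjusted p under 0.05, and 0 with the block, with 494 to 1527 at that level. DESeq2 called 2 in CU2 (LINC01016 and ENSG00000233183, both lower), 1 in CU1ENC (BCYRN1, log2 fold change 4.20, adjusted p = 4.89e-05) and 0 in the rest. With the block DESeq2 again called BCYRN1 in CU1ENC, and it added LINC01016 in CU1ENU. With only the compared groups in the fit, edgeR called 1 gene higher in CU1ENC. Gene lists moved by small amounts, with 0 members passing over all genes or adjusted over the list alone. T2 stood higher for ribosomal proteins (77 of 78 positive, median 0.12, camera adjusted p = 1.14e-17), respiratory subunits (58 of 60, 0.11, 2.99e-14), cholesterol genes (22 of 25, 0.10, 1.55e-05) and interferon-stimulated genes (30 of 43, 0.14, 0.0197). It stood lower for immediate-early genes (1 of 31 positive, median -0.19, 5.67e-08), NF-kB genes (3 of 19, -0.18, 0.00122), the integrated stress response (10 of 35, -0.06, 0.0181) and mitochondrially encoded genes (0 of 13, -0.17, 0.0181). All 8 calls ended with an estimated correlation, with adjusted p between 0.217 and 0.978. Examples were RPL36 (0.22 ± 0.10), ATP5MC2 (0.16 ± 0.06), NSDHL (0.25 ± 0.09), IFNB1 (0.47 ± 0.72), FOSB (-0.63 ± 0.18), NFKB1 (-0.19 ± 0.08), SESN2 (-0.19 ± 0.08) and MT-ND2 (-0.27 ± 0.24). For the interferon list the replicates went opposite ways, with T2 minus the mean of the others at -0.311 in replicate 1 and 1.398 in replicate 2. The ribosomal and respiratory shifts of T2 lay almost wholly in replicate 1, at 0.211 and 0.202. In replicate 2 they were 0.019 and 0.023.

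CU2 stood higher for interferon-stimulated genes (43 of 43 positive, median 0.64, camera adjusted p = 2.55e-11) and NF-kB genes (17 of 19, 0.14, 0.00553) and lower for ribosomal proteins (4 of 78, -0.05, 5.11e-05) and respiratory subunits (13 of 60, -0.04, 0.00553). All 4 ended with an estimated correlation (adjusted p between 0.721 and 0.804). Here CCL5 measured 1.08 ± 0.65, NFKB1 0.14 ± 0.08, RPS13 -0.13 ± 0.09 and NDUFS5 -0.15 ± 0.08. The mean of the ribosomal list differed by 0.016 in replicate 1 and -0.11 in replicate 2. CU1ENU stood lower for ribosomal proteins (9 of 78 positive, median -0.06, 6.64e-07), interferon-stimulated genes (0 of 43, -0.52, 0.000693) and respiratory subunits (16 of 60, -0.05, 0.00110), with IFNL1 at -1.52 ± 1.06, RPL36 at -0.18 ± 0.10 and COX8A at -0.18 ± 0.10. These 3 calls had adjusted p = 0.925 with an estimated correlation. The ribosomal mean of CU1ENU differed by -0.114 in replicate 1 and -0.013 in replicate 2, and the respiratory mean by -0.085 and -0.018. T1 was higher for immediate-early genes alone (27 of 31 positive, median 0.14, 5.67e-05, and adjusted p = 0.563 with an estimated correlation), with MAFF at 0.43 ± 0.17, and CU1 had 0 called lists.

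CU1ENC had 6 called lists against the other 5. Kidney tubule markers (5 of 6 positive, median 0.30, camera adjusted p = 0.0234; AQP1, a water channel, 0.52 ± 0.23), histones (20 of 27, 0.08, 0.0234; H2BC13 0.75 ± 0.39), mitochondrially encoded genes (13 of 13, 0.16, 0.0260; MT-ND2 0.19 ± 0.23) and immediate-early genes (25 of 31, 0.09, 0.0260; FOSB 0.39 ± 0.16) were higher. Interferon-stimulated genes (2 of 43 positive, median -0.30, 0.0234; IFNB1 -0.65 ± 0.82) and heat shock genes (2 of 22, -0.04, 0.0234; DNAJA1 -0.09 ± 0.06) were lower. All 6 had adjusted p = 0.955 with an estimated correlation. By replicate number the list means went opposite ways for heat shock genes (-0.17 in replicate 1 and 0.022 in replicate 2) and immediate-early genes (-0.016 and 0.16). The block added, in T1, the integrated stress response (up, adjusted p = 0.0127), ribosome biogenesis (up, 0.0262) and p53 targets (down, 0.0470), and in CU1 interferon-stimulated genes (down, 0.0154). It further added in T2 the unfolded protein response (down, 0.0399) and G1/S genes (up, 0.0483), in CU2 ribosome biogenesis (down, 0.0280) and fibroblast markers (up, 0.0465), and in CU1ENC G2/M genes and SR proteins and hnRNPs (down, 0.0440 each). All of these additions ended with an estimated correlation in the blocked fit, with adjusted p between 0.490 (G1/S in T2) and 0.907 (interferon in CU1). The genes of lowest p within the limits for naming were THAP8 in T1 (-0.61 ± 0.18), FOXP4-AS1 in T2 (0.80 ± 0.21) and MT-TP in CU1 (-0.89 ± 0.28). For the other isoforms they were PSD3 in CU2 (-0.25 ± 0.07), BCYRN1 in CU1ENC (4.19 ± 0.57) and the pseudogene RPL18AP3 in CU1ENU (1.99 ± 0.44). Each had an adjusted p of 1.00. RPL18AP3 turned to -0.27 without CU1ENU replicate 2, and IFNB1 in CU1ENC turned to 0.14 without CU1ENC replicate 2.

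Fold changes of the 6 isoforms over the shared empty vector libraries resembled each other across 14634 genes, with a mean r of 0.470 over 15 pairs of isoforms. These are correlations across genes, which are not independent replicates. Simulated unchanged groups set against simulated shared controls gave a mean r of 0.503, with means from 0.477 to 0.528 over 20 simulations. The mean covariance was 0.0117 against 0.0161 in simulation, a difference of -0.00446, and the same sign was shared by 66.9% against 66.7% of genes. Calls in 2 or more isoforms were LINC01016 in 6 and ENSG00000233183 in 5, the transfected gene and the gene that overlaps it. Splitting 2 control libraries leaves 1 in each part, so no split was made. The observed mean r lay below that of every simulation, so the simulated noise differed from that of the data. The simulation therefore cannot tell whether the isoforms share a small response.

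Around the endogenous LINC01016 gene, 34 annotated genes other than ENSG00000233183 lie within 500 kb, and 0 of the 18 tested ones passed in any isoform, with or without the block. The largest absolute log2 fold change there was 1.29 (GRM4, a glutamate receptor gene, -1.29 in CU1). HMGA1, a chromatin protein gene, and KIFC1, a kinesin gene, ranged from -0.01 to 0.12 and from -0.03 to 0.03 over the 6 isoforms.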

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

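The 3 tests of explanations here were chosen only after the result was seen. The mean log2 level of the 43 interferon-stimulated genes was higher in replicate 1 than in replicate 2 in 7 of 7 transfected groups, by 0.737 (T2) to 3.41 (T1) with a median of 2.08. In parental cells replicate 1 minus replicate 2 was -0.339. It stood out because all transfected groups moved one way and the parental group the other. The difference was not tested, since 1 untransfected group among 8 cannot give an exact permutation p below 0.125. Single genes show the size: IFIT1, chosen after its counts were seen, had 9890 and 367 counts in T1 and 154 and 211 in parental cells.

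A replicate difference that reached every culture stays open, since the parental value (-0.3394) is part of the pattern itself and rests on 1 pair of libraries. A stronger ATF4 response in replicate 1 is argued against by the integrated stress response list, whose median difference over the 7 groups was 0.0186 (0.006 to 0.106). That list does not cover other forms of stress. Over the 8 groups, p53 and NF-kB genes were called higher in replicate 1, and unfolded protein response and heat shock genes lower. More plasmid in replicate 1 stays open: LINC01016 was higher there in 6 of 6 isoforms, by 1.06 to 1.77-fold, but over the isoforms its difference did not track that of the list (Spearman rho = -0.0286, exact permutation p = 1.00; Pearson r = 0.285, exact permutation p = 0.604; 2 relations). A response to transfected DNA that varied with whatever the replicate numbers mark may be the source, as a hypothesis. The labels give no batch to test it.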

How the results depend on the processing

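DESeq2 with the block and the fit of only the compared groups with the block were chosen after seeing the data, and the alternatives for single isoform genes cover the narrowed set of names. RLE normalization kept all 160 named results and changed 1 gene count, empty vector against parental cells, to 3056. For empty vector against parental cells the count of 3092 became 6626 with the replicate block, 5367 in DESeq2 with the block, 7483 with only those 4 libraries and the block, and 693 with a 2-fold minimum. Leaving out each library in turn gave 1365 to 3196. Leaving a library out keeps 1 sample in a group, which is assumed to vary like the others.

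For isoforms against empty vector, the replicate block lowered the count to 1 in T2 and 1 in CU1, and with the pairing in DESeq2 CU2 had 2. The block moved lists to 8 in CU2, 5 in CU1ENC, 5 in CU1ENU, and against the other 5 isoforms to 4 in T1 and 1 in CU1. Apart from the calls named beside the results, it changed no call of a named gene. Leaving LINC01016 out removes its own call and left 1 gene in T1, 1 in T2, 0 in CU1, 0 in CU2, 1 in CU1ENC, 1 in CU1ENU and 1 for the mean of 6. In CU1 the antisense gene also lost its call, and the cause was not tested. With only the compared groups in the fit, CU1 had 1, CU2 2, CU1ENC 1 and CU1ENU 1, and CU1ENC against the other 5 had 1. DESeq2 gave 2 in CU2, 2 in CU2 against the other 5, 1 in CU1ENC against the other 5 and 2 in the F-test. With the block, DESeq2 gave 2, 1 and 1 for CU2, CU1ENC and CU1ENU against the other 5. The cause was not tested. Leave-one-out counts ran from 1 to 2 for T1, T2, CU1, CU2, CU1ENC and the mean of 6, from 1 to 3 for CU1ENU, from 0 to 1 for CU2, CU1ENC and CU1ENU against the other 5 and for the F-test, and stayed 0 for T1, T2 and CU1 against the other 5.

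Without the low-count filter, empty vector against parental cells had 3381 genes, T1 had 32 genes, T2 35, CU1 17, CU2 73, CU1ENC 7, CU1ENU 2 and the mean 34. Against the other 5, T1 had 3, T2 2, CU1 2, CU2 61, CU1ENC 8 and CU1ENU 27, and the F-test had 63. In that fit the prior degrees of freedom became infinite for all 38201 genes, so the gene's own spread was ignored, and 38 of the 73 genes in CU2 were interferon-stimulated ones that differ widely between replicates.

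An estimated correlation left 2 called lists for empty vector against parental and 0 for T1, T2, CU1, CU2, CU1ENU, the mean, and for T1, T2, CU2, CU1ENC and CU1ENU against the other 5. With parental cells as the control, lists called were 14 in T1, 14 in CU1, 15 in CU2, 13 in CU1ENC, 15 in CU1ENU and 15 for the mean. Genes were 3758 in T1, 2278 in T2, 2593 in CU1, 3177 in CU2, 3362 in CU1ENC, 2888 in CU1ENU and 5657 for the mean, a change that follows from adding the effect of empty vector over parental cells. That control turned GINS2 to -0.053, FDPS to -0.25, ATP5PD to -0.17 and FOSB to 1.20 in T2, and PCNA to -0.23 and DPH5 to -0.027 in the mean. Without empty vector replicate 1, MT-ND2 in T2 turned to 0.088, and without replicate 2 it was -0.62. Without CU1ENC replicate 2, IFNB1 in CU1ENC against the other 5 turned to 0.14, and without replicate 1 it was -2.52. Without CU1ENU replicate 2, RPL18AP3 in CU1ENU turned to -0.27, and without replicate 1 it was 2.84. Limited power bears on all counts of 0: in the T1 simulation without the block 20.9% of 1.5-fold and 50.8% of 2-fold changes were called. With the block, at the same depth and 2 replicates, 46.3% and 68.7% were called, with 13 false calls. Leaving the block out is therefore one of the limits. The simulated replicate difference was the same in every group, while that of the real interferon list varied between groups, so these shares are approximate.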

Other observations

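The tests of antisense reads by strand, of snoRNA hosts and of LINC01016 level were chosen only after the result was seen. Replicate number moved many gene groups beyond the interferon list. Over the 8 groups with group as a term, edgeR called 3455 genes higher in replicate 1 and 3478 higher in replicate 2, with 354 of them changed at least 2-fold. Of 25 p53 target genes 20 were higher in replicate 1 and 1 lower (median 0.33, camera adjusted p = 2.37e-18, and adjusted p = 0.0535 with an estimated correlation). Interferon-stimulated genes were higher in 42 of 43 (median 1.87, 1.15e-12, and adjusted p = 0.505 with an estimated correlation). Lower in replicate 1 were G2/M genes (22 of 30, median -0.16, 1.01e-11), ribosome biogenesis genes (23 of 30, -0.19, 3.12e-10), the unfolded protein response (16 of 25, -0.13, 2.44e-05) and SR proteins and hnRNPs (21 of 31, -0.12, 2.34e-05). None of these 4 held with an estimated correlation, where adjusted p was 0.150, 0.125, 0.305 and 0.537. Also called were NF-kB genes (up, camera adjusted p = 0.00207), mitochondrially encoded genes (up, 0.00564), kidney tubule markers (up, 0.0252), neuronal genes (up, 0.0374), G1/S genes (down, 0.000783), respiratory subunits (down, 0.00109), immediate-early genes (down, 0.00310) and heat shock genes (down, 0.0106). These 8 had adjusted p between 0.150 and 0.611 with an estimated correlation.

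Among single genes named by size, the imprinted non-coding RNA MEG3 (log2 difference 2.47, adjusted p = 1.20e-11) and the interferon-inducible genes XAF1 (3.06, 0.00451), MX2 (2.87, 0.00760) and BST2 (2.64, 0.00427) were higher in replicate 1. The peptide hormone gene NPPB (-1.47, 9.70e-11), endothelin gene EDN1 (-1.18, 7.71e-10) and matricellular CCN2 (-0.92, 0.000592) were lower. Depth does not account for it, since 6816 genes, against 6933 at full depth, still differed after every library was thinned to the smallest total. A trend with GC content or gene length is argued against as the whole cause by the 7517 genes found after its correction, 6295 of them among the 6933. Chance is argued against: of 60 splits with 1 library of every group on either side, only the real one gave as many genes. It had 6768 in the non-robust fit used for all 60, and the highest other, which swapped only the parental pair, gave 2160. A share of 1 in 60 is the smallest that these splits can give. What the numbers mark is not in the labels, and no biological explanation was tested.

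Counts of ENSG00000233183 rose with LINC01016 although the plasmid carries LINC01016, and 94.09% of the exonic bases of that gene lie outside LINC01016 exons. Gene totals do not show where its reads fell, so induction of the chromosomal gene cannot be told apart from reads on the shared bases. Leakage of the strand marking may be a source: if all antisense reads lay on the shared bases and LINC01016 reads were spread evenly, the lowest share per shared base would be 17.1%, and in 770 other opposite-strand pairs of high expression the 10th percentile of the share taken in that way was 4.257% (bootstrap 95% interval 2.80 to 6.36). That interval spans the bound of 4.28% that would have spoken against leakage. An earlier version, on the share of pairs below 17.1%, gave 22.5% (173 pairs), between its bounds of 10% and 50%, and decided nothing. The percentile replaced it after that outcome, and the bootstrap was added after the percentile, which lay just under the bound, was seen.

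A hypothesis from SNHG15 and SNHG17 was that snoRNA host genes rose in empty vector cells as a class. Of 25 other hosts 8 rose, 0 fell and 23 were positive, with a median of 0.4407, above 0.17, the upper 95% limit for 10000 expression-matched random lists (permutation p = 1e-04, the smallest they can give). With the replicate block 12 of these hosts rose and 1 fell. Camera with an estimated correlation gave p = 0.0485, and p = 0.0927 with the replicate block, so the data leave the hypothesis open. The criterion was tightened to need both values after they were seen.

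Whether more LINC01016 RNA goes with less interferon-stimulated expression was asked within each replicate number over the 6 isoforms. Pearson r was -0.539 in replicate 1 (exact permutation p = 0.274) and -0.798 in replicate 2 (0.0486), with Benjamini-Hochberg values of 0.274 and 0.0972 over 2 relations. Spearman rho was -0.60 (exact permutation p = 0.242) and -0.486 (0.356), each 0.356 after adjustment. Without CU2 and CU1ENU, the isoforms farthest from the median, r became 0.434 and -0.94, so in replicate 1 the relation rests on those isoforms. No effect of LINC01016 level can be read from this.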
